A study of Vitis vinifera with 12 samples.

How the data were processed

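RNA was measured in young leaves and fruit peels of Bangalore blue, Red globe and Dilkhush, with 2 libraries for each cultivar and tissue. Total RNA was extracted with a plant RNeasy kit and libraries were made with a directional (strand-keeping) mRNA kit, per the labels' protocols. TopHat2 2.1.1 and Cufflinks 2.2.1 are named, per the submitters' processing notes, which were read without the role of each tool. The genome build, the annotation, how repeated alignments were shared out and how the 2 libraries of a group were merged are not given in the sources used here. The deposited values are RPKM in 2 tables, 1 for peel and 1 for leaf, with 3 cultivar columns each, per the file headers. RPKM divides reads by transcript length and by the reads of the whole column, so a gene taking a large share lowers every other value, and values from separate tables are not on a shared scale. Near-identical gene copies, rows carrying several gene names (672 in peel and 782 in leaf) and names repeated on several rows (304 and 586) are uncertain, since the counting may have split or shared their reads. Sequencing depth is unknown: low values were examined for steps of whole reads and none was found, so no counting interval or detection limit is given, and a value of 0 is described as listed at 0.

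Columns were tied to groups by cultivar and tissue initials matching the sample titles. Because each cultivar had 1 value per tissue, the planned linear model (limma) with 2 libraries per group could not be fitted, and the plan written before the data were examined for that case was followed. Rows were called where the difference of log2(RPKM + 1) was at least 2 in size, which is 4-fold, with an RPKM of at least 10 in the higher cultivar. On this scale differences of genes with low values are understated. There were 6 comparisons, 3 in each tissue, and no p-values. The difference between tissues was described by counts over shared rows and not tested.

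Gene names came from the files and, for rows named only by a LOC number, from a RefSeq gene table of assembly GCF_030704535.1. Of 25116 LOC numbers 22516 were in that table and 51 had a symbol or synonym. No coordinates are given, since the build of the files is not known. A symbol was available for 326 peel rows and 327 leaf rows, so named genes are a small part of each table. Gene lists were fixed before the data were examined: 19 lists, for anthocyanin, early flavonoid, flavonol, proanthocyanidin, MYB and bHLH activators, MYB repressors, phenylpropanoid, stilbene, lignin, photosynthesis, defence, heat shock, cell wall, sugar transport, wax and cutin, terpene, seed, cell cycle and small RNA machinery genes. The files pair no descriptions with rows, so members were matched by symbol or synonym; this matching was drawn up after the files were seen and without regard to values. Symbols matched no row for the last 5 lists, so markers of other tissues such as seed were not analysed here.

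A list row was measured where at least 1 cultivar reached an RPKM of 1. For lists with at least 3 measured rows the median log2 difference was placed among 10000 random lists of the same size, drawn from the 200 rows nearest in mean expression to each member. This percentile describes these columns and is not a test of the cultivars. In 8 lists and 6 comparisons, 19 of 48 medians lay outside the central 95%, where 2.4 would by chance if rows within a list varied independently. Genes of a pathway and close copies with shared reads may vary together, so the 2.4 can be too low. Named genes followed a rule set beforehand: every measured anthocyanin, MYB activator and MYB repressor row that was called or reached 10 RPKM in either cultivar, the 6 largest differences each way among called rows with a name (4 each way between Bangalore blue and Red globe, or as many as there were), and 2 to 4 members of each other list by size of difference. Lists with fewer rows give what they have, at most 2 unnamed rows each way were printed, and further genes such as CHLH, chosen after their values were seen, are given beside them.

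Alternatives fixed beforehand were a pseudocount of 0.1, no floor, a filter of 5 RPKM in 2 columns, quantile normalization and scaling to equal medians. Added after the data were seen were counts without transfer RNA rows and rows of several names, scaling to an equal total without transfer RNA, and the filters and equal-median scaling for the lists. The calling and list steps were tried on simulated pairs of columns. Both columns of a pair were made from the real column of the second cultivar named, with noise (SD 0.3 on the log2 scale). In the first column 200 rows were changed 8-fold. For Bangalore blue against Dilkhush 96.5% of changed rows were recovered in the peel table of 25210 rows. In the leaf table of 25253 rows it was 92.5%. Each had 0 false calls, which noise this small all but fixes in advance. The real columns spread more: for Bangalore blue against Dilkhush peel the 95th percentile of absolute differences at the floor was 2.26. False calls among the cultivars were therefore not estimated. For Red globe against Dilkhush recovery was 95% in peel and 97% in leaf, and for Bangalore blue against Red globe 92% and 96.5%. Both comparisons with Dilkhush started from the same column, so their recoveries differ only by random draws. No run used Bangalore blue values. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.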

Results

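Messenger RNA was sequenced from young leaves and from fruit peels of 3 grape (Vitis vinifera) cultivars, Bangalore blue, Red globe and Dilkhush, which the series describes as differing in anthocyanin content. Anthocyanins are the red to blue flavonoid pigments of grape skin. Each cultivar and tissue was represented by 2 libraries, 12 in all, which fall into 6 groups. The deposited values were RPKM (reads normalized to transcript length and to the mapped reads of the library), with 1 column for each cultivar in each tissue, so every value below is the authors' value for a cultivar and has no replicate error. No difference was therefore tested against replicate spread, and no p-value is given. A gene was called higher or lower where the cultivars differed at least 4-fold on the RPKM + 1 scale with an RPKM of at least 10 in the higher one, which describes these columns and not the cultivars at large.

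There were 25210 rows for peel and 25253 rows for leaf. The sequencing depth behind the columns is unknown. Median RPKM over all rows was 2.63 in Bangalore blue, 3.06 in Red globe and 2.99 in Dilkhush peel, and 5.83, 6.04 and 5.95 in the leaves in the same order. Rows listed at 0 made up 19.6% of the Bangalore blue peel column, 17.2% of Red globe and 16.9% of Dilkhush. Rows named as transfer RNA took 33.6% of the summed RPKM in Red globe peel, against 13.8% in Bangalore blue and 20.7% in Dilkhush peel, and between 11.6% and 13.3% in the leaf columns. None of these rows was called in any comparison. Nearly all of the peel share came from the row TRNAS-GGA, at 117402 RPKM in Bangalore blue, 358749 in Red globe and 201194 in Dilkhush. A share of summed RPKM is not a share of reads, since RPKM divides by transcript length. The peel and leaf tables were normalized separately, so cultivars were compared within a table.

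The first question was how peel of Bangalore blue differed from peel of Dilkhush. The late anthocyanin genes stood far higher in Bangalore blue. GST4, a glutathione S-transferase needed to move anthocyanins into the vacuole, was 2246 RPKM against 9.86 in Dilkhush (log2 difference 7.69). UFGT, which attaches glucose to anthocyanidins, was 297 against 2.09 RPKM (6.59). FAOMT, which methylates anthocyanins, was 50.8 RPKM in Bangalore blue and listed at 0 in Dilkhush. F3'5'H, the hydroxylase that opens the branch to the blue delphinidin pigments, was 37.4 against 0.034 RPKM (5.22).

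All 7 measured rows of the anthocyanin list were higher in Bangalore blue peel, and 5 of them were called. Their median log2 difference was 5.22, at percentile 100 among 10000 random lists of equal size and like expression. LDOX, the anthocyanidin-forming dioxygenase, was 2010 against 171 RPKM (3.55) and was called. DFR, the reductase before it, was 369 against 108 RPKM (1.77), and F3'H, on a row shared with another gene identifier, was 42.0 against 18.0 (1.18), both short of the 4-fold size. An eighth row, a further F3'5'H copy, was listed at 0 in every peel column.

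The early flavonoid genes that feed the same pathway were also higher. All 5 rows had a larger RPKM in Bangalore blue peel, 2 were called, and the list median was 1.51 (percentile 99.97). CHS3, a chalcone synthase, was 2096 against 49.7 RPKM (5.37), and the flavanone hydroxylase F3H was 277 against 7.48 (5.03). A pair of further CHS rows was at 482 against 170 and 151 against 52.4 RPKM, and the chalcone isomerase CHI was at 291 against 127. CHS rows are close copies, and reads shared between them cannot be assigned with certainty. The upstream phenylpropanoid list had 2 measured rows, too few for a percentile: 4CL was 23.8 against 7.25 RPKM, and 1 PAL row was below 1 RPKM in both cultivars.

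Of the transcription factors, the row of the anthocyanin MYB activators (LOC100853472, for which the reference gives the synonyms mybA, MybA1 and MybA3) was 102 RPKM in Bangalore blue and 22.5 in Dilkhush (2.14) and was called. The bHLH partner MYC1 was 10.31 against 6.27 RPKM, and the remaining activator row, MYCA1, was below 10 RPKM in both. The activator list median of 0.64 lay inside the central 95% of random lists (percentile 95.94). Among MYB repressors, MYBC2-L1 was 92.0 against 21.5 RPKM (2.05) and was called, MYB4A was 141 against 77.3 (0.86), and the third measured row was below 10 RPKM in both. The repressor list median was 0.86 (percentile 97.86), and it lay inside the central range, at percentile 96.52, with a pseudocount of 0.1.

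**Figure D1:**
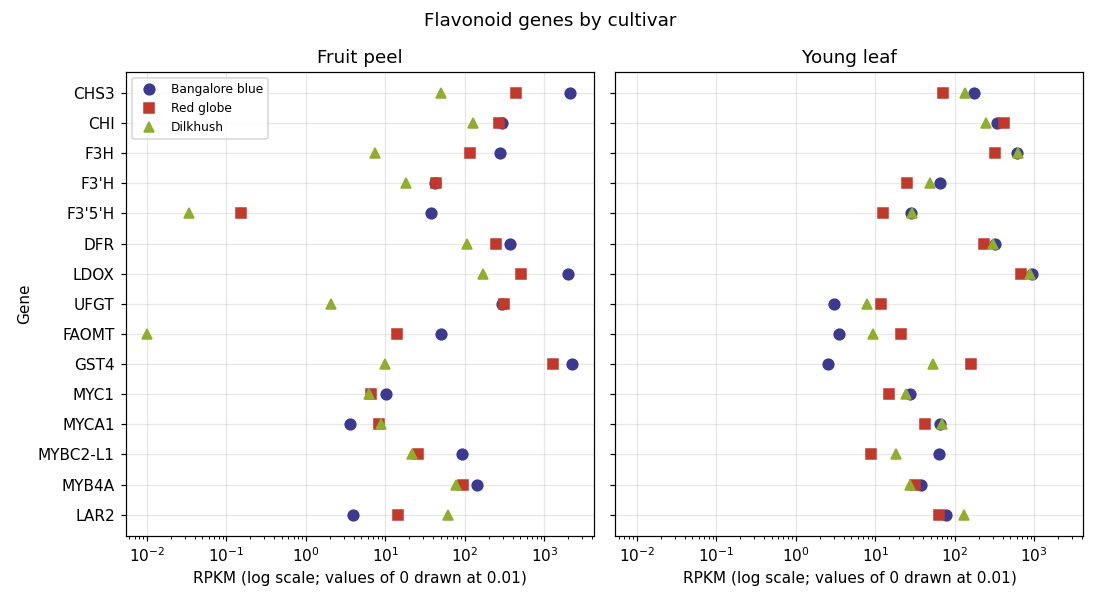
RPKM on a log axis for flavonoid genes in fruit peel (left) and young leaf (right), with 1 point for each cultivar, being the authors' value for that cultivar; values of 0 are drawn at 0.01. In peel, GST4, UFGT and FAOMT of Dilkhush (triangles) lie far to the left of both other cultivars, and in leaf GST4 of Bangalore blue (2.58) lies left of Dilkhush (53.2) and Red globe (162).

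Genes lower in Bangalore blue peel included RD22-C, of a dehydration-responsive family, at 0.50 against 246 RPKM (-7.37), and the pathogenesis-related PR-1 row at 5.98 against 670 (-6.59). IFRL6, an isoflavone reductase-like gene, was 12.7 against 189 RPKM, and GFH2 was 12.8 against 172. LAR2, a leucoanthocyanidin reductase of the proanthocyanidin (tannin) branch, was 3.92 against 61.8 RPKM (-3.68). All 3 rows of the proanthocyanidin list were lower in Bangalore blue, with a median of -0.70 (percentile 4.78, inside the central range, or 2.06 with a pseudocount of 0.1) and MYBPA1, a regulator of that branch, at 6.33 against 10.903 RPKM. VvCASPL2C1, a Casparian strip membrane protein-like gene, was 0.62 against 13.7 RPKM. GST3, another glutathione S-transferase, was in contrast 44.9 RPKM in Bangalore blue and listed at 0 in Dilkhush.

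Stilbene synthases, which make resveratrol from the substrates chalcone synthase also uses, had a median of 1.98 (percentile 99.73), although none of the 3 rows reached 10 RPKM in these cultivars. An STS row was 7.33 against 0.43 RPKM and VINST1 was 3.48 against 0.13. The 14 measured defence genes had a median of 0.45 (percentile 99.75) with 9 higher and 5 lower. PR10.3 was 257 against 42.4 RPKM (2.57), and the row of the thaumatin-like TL3, which carries 2 gene identifiers, was 23183 against 3779. Sugar transport genes had a median of -0.16 (percentile 33.2) and none was called. The hexose transporters HT4 and HT6 were 8.89 against 2.17 and 145 against 364 RPKM. FLS1, the flavonol synthase, was 78.9 against 40.6 RPKM, and MYB12 was below 1 RPKM in all peel columns. Of the lists with fewer than 3 rows, the photosystem II genes PSBP1 and PSBP2 were 350 against 483 and 15.3 against 22.4 RPKM. The lignin gene CCOAMT was 12.5 against 13.0, the pectate lyase PL1 442 against 883 and the heat shock gene HSP101 18.6 against 19.7.

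In all, 226 rows were called higher and 356 lower in Bangalore blue than in Dilkhush peel, of 9551 rows with an RPKM of at least 10 in the higher cultivar. Most carry no gene name: 20 of the rows called higher and 15 of those called lower had a symbol. Among unnamed rows, LOC100241269 was 2108 RPKM in Bangalore blue and listed at 0 in Dilkhush, while LOC100852930 was 0.59 against 825. The median log2 difference of all 9551 rows was -0.09. The total of 582 became 878 without a floor on RPKM and 379 where 2 columns had to reach 5 RPKM.

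In Red globe peel, too, the late anthocyanin genes stood far above Dilkhush. GST4 was 1279 against 9.86 RPKM (6.88), UFGT was 308 against 2.09 (6.64), and FAOMT was 14.1 in Red globe and listed at 0 in Dilkhush. F3'5'H was near 0 in both, at 0.15 and 0.034 RPKM. LDOX was 510 against 171 RPKM (1.57), DFR was 244 against 108 (1.17), and F3'H was 42.8 against 18.0, none of which was called. All 7 measured anthocyanin rows were higher in Red globe, 3 were called, and the list median was 1.57 (percentile 99.99), or 2.74 where 2 columns had to reach 5 RPKM.

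The early flavonoid list had a median of 1.08 (percentile 99.92), with CHS3 at 443 against 49.7 RPKM (3.13) and F3H at 117 against 7.48 (3.80) called higher. The mybA row was 36.1 against 22.5 RPKM (0.66), both bHLH rows were below 10 RPKM, MYB4A was 93.4 against 77.3 (0.27) and MYBC2-L1 was 25.7 against 21.5 (0.25). Neither regulator list stood apart, with percentiles of 62.82 for activators and 81.21 for repressors. The proanthocyanidin median was -0.85 (percentile 3.02, or 1.61 with a pseudocount of 0.1), with LAR2 at 14.3 against 61.8 RPKM (-2.04) called lower, LAR1 at 0.63 against 1.94 and MYBPA1 at 13.5 against 10.903.

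Stilbene synthase rows were all called higher in Red globe peel, with a median of 3.62 (percentile 99.97). The largest was an STS row at 26.4 against 0.43 RPKM (4.26), and VINST1 was 13.0 against 0.13. These are near-identical copies, so reads could be split among them. CTR7 was 45.1 against 0.37 RPKM (5.07). The hexose transporter HT5 was 28.0 against 1.03 RPKM (3.84) and the cell wall invertase CWINV was 24.7 against 2.55 (2.86), whereas the sugar transport list as a whole had a median of -0.58 (percentile 1.2). VVSUC27 was 2.13 against 11.5 RPKM and HT6 was 143 against 364.

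Lower in Red globe peel were the PR-1 row at 0.71 against 670 RPKM (-8.62) and RD22-C at 1.04 against 246 (-6.92). The aquaporins PIP1;2, on a shared row, and TIP1;1 were 43.1 against 609 RPKM (-3.79) and 6.28 against 68.4 (-3.25). PR10.7 was 3.92 against 52.8 RPKM and the kinase gene CIPK08 was 2.07 against 15.5. The defence list nevertheless had a median of 0.45 (percentile 99.84), with 10 of 14 rows higher, among them PR10.3 at 424 against 42.4 RPKM (3.29) and CHIT3 at 11.7 against 0.73 (2.87), both called. FLS1 was 22.1 against 40.6 RPKM, 4CL 20.7 against 7.25, PAL 1.29 against 0.13, PSBP1 239 against 483, PSBP2 10.87 against 22.4, PL1 253 against 883, CCOAMT 17.8 against 13.0 and HSP101 11.7 against 19.7.

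Of 9594 rows at the floor, 232 were called higher and 321 lower in Red globe than in Dilkhush peel, 553 in all, and the count was 350 where 2 columns had to reach 5 RPKM. With columns scaled to an equal total without transfer RNA, a setting chosen after the data were seen, 272 were higher and 272 lower. The percentile of the defence list moved to 90.22 where 2 columns had to reach 5 RPKM, and that of the sugar transport list to 4.63, or to 15.29 (median -0.15) with no filter on low values.

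Bangalore blue and Red globe peel, compared directly, differed most among named genes in F3'5'H, at 37.4 against 0.15 RPKM (5.06), and GST3, at 44.9 against 0.44 (4.99). UFGT was 297 against 308 RPKM and F3'H 42.0 against 42.8, while FAOMT was 50.8 against 14.1 (1.78), LDOX 2010 against 510 (1.98), GST4 2246 against 1279 (0.81) and DFR 369 against 244 (0.60). The anthocyanin median was 0.81 (percentile 99.47), with 5 rows higher and 2 lower, or 6 and 1 after scaling to equal medians. F3'5'H was the 1 row called.

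Early flavonoid rows had a median of 1.07 (percentile 99.56), with CHS3 called at 2096 against 443 RPKM (2.24) and F3H at 277 against 117. All 5 were higher in Bangalore blue, or 4 after quantile normalization. The mybA row was 102 against 36.1 RPKM (1.48), MYC1 was 10.31 against 6.67, MYBC2-L1 was 92.0 against 25.7 (1.80) and MYB4A was 141 against 93.4 (0.59), none called. Activator and repressor medians were at percentiles 93.44 and 92.81. The proanthocyanidin median was -0.98 (percentile 2.33), with LAR2 at 3.92 against 14.3 RPKM and MYBPA1 at 6.33 against 13.5, and it was at percentile 3.55 with a pseudocount of 0.1. Stilbene synthases were lower in Bangalore blue, with a median of -1.64 (percentile 1.07) and no row called. An STS row was 7.33 against 26.4 RPKM and VINST1 was 3.48 against 13.0.

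Thaumatin-like TL1 was 4081 RPKM in Bangalore blue and 369 in Red globe peel (3.46), and PR10.7 was 58.1 against 3.92 (3.59). Lower in Bangalore blue were IFRL6 at 12.7 against 157 RPKM (-3.53), IFRL4 at 5.80 against 61.0, the lipoxygenase LOX at 5.64 against 59.2, and MLO15, of a family linked to powdery mildew susceptibility, at 8.90 against 83.0. The defence list had 7 rows higher and 7 lower, with 3 called higher and 2 called lower and a median of -0.22 (percentile 10.36, or 0.36 with no filter on low values). Sugar transport genes had a median of 0.07 (percentile 59.38), with HT4 at 8.89 against 0.32 RPKM, under the floor. HT5 at 4.004 against 28.0 and CWINV at 3.61 against 24.7 were called lower in Bangalore blue. FLS1 was 78.9 against 22.1 RPKM, 4CL 23.8 against 20.7, PAL 0.25 against 1.29, PSBP1 350 against 239, PSBP2 15.3 against 10.87, PL1 442 against 253, CCOAMT 12.5 against 17.8 and HSP101 18.6 against 11.7. Of 9459 rows at the floor, 226 were called higher and 271 lower, 497 in all, or 797 without the floor. The unnamed LOC100246060 was 5553 RPKM in Red globe and listed at 0 in both other peel columns.

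**Figure D2:**
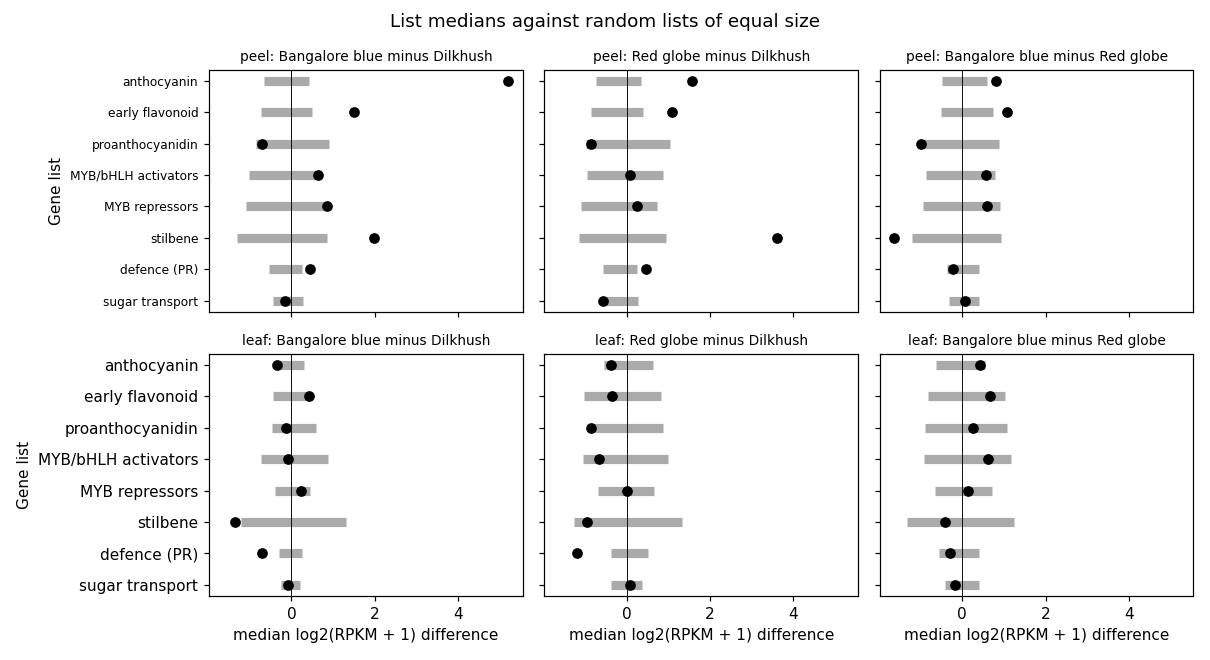
Median log2(RPKM + 1) difference of each gene list (black points) for 3 cultivar comparisons in peel (top) and leaf (bottom), with the central 95% of medians of random lists of the same size and like expression (grey bars). The anthocyanin point lies at 5.22 for Bangalore blue minus Dilkhush in peel and at -0.36 for the same comparison in leaf.

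In young leaves the anthocyanin genes did not repeat the peel order. Between Bangalore blue and Dilkhush, LDOX was 927 against 881 RPKM, DFR 320 against 302, F3'5'H 28.1 against 29.3 and F3'H 64.7 against 48.7. GST4 was 2.58 in Bangalore blue and 53.2 in Dilkhush (-3.92) and was the 1 anthocyanin row called, lower in Bangalore blue. UFGT at 3.03 against 7.87 RPKM and FAOMT at 3.47 against 9.32 were below 10 RPKM in both, as were 2 further F3'5'H rows. The list median was -0.36 (percentile 2.11, with 3 of 9 rows higher), which moved to percentile 10.51 where 2 columns had to reach 5 RPKM. This median fell on the further F3'5'H row that carries several gene names, at 5.14 against 6.85 RPKM.

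The early flavonoid median was 0.42 (percentile 97.87), with CHS at 836 against 559 RPKM, CHI at 342 against 247, CHS3 at 176 against 135 and no row called. The mybA row was listed at 0 in Bangalore blue leaf and was 0.58 in Dilkhush. MYC1 was 27.6 against 24.7 RPKM, MYCA1 64.8 against 68.5, MYBC2-L1 63.0 against 18.4 (1.72), MYBC2-L2 45.0 against 43.0, MYB4A 37.2 against 27.6 and MYB4B 16.0 against 18.1, and none was called. Percentiles of the activator, repressor, proanthocyanidin and sugar transport lists were 43.87, 88.86, 27.28 and 32.26. The activator list did not hold the leaf activators MYBA6 and MYBA7, so its percentile leaves them out. They were 6.29 against 17.4 and 0.68 against 4.07 RPKM, both lower in Bangalore blue. LAR1 was 62.7 against 28.3 RPKM and LAR2 76.5 against 130, while CWINV was 12.4 against 40.3, the invertase NIN1 49.2 against 15.9 and HT5 24.0 against 51.4.

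Named rows with the largest excess in Bangalore blue leaf came next. The dehydrin DHN1 was 72.0 against 0.46 RPKM (5.64), NCED1, an enzyme of abscisic acid synthesis, was 65.3 against 1.46 (4.75), and the cold-response factor CBF4 was 16.2 against 0.28 (3.75). CCD4b, a carotenoid cleavage dioxygenase, was 19.9 against 1.17 RPKM, GST3 was 18.4 against 1.40 and BAP1 was 30.4 against 3.12.

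The defence list had a median of -0.70 in Bangalore blue against Dilkhush leaf, below all random lists (percentile 0). Of 13 measured rows 9 were lower and 4 higher, with 3 called lower and 2 called higher. All 7 measured PR-1 and PR10 rows were among the lower ones. PR10.4 was listed at 0 in Bangalore blue and was 27.9 RPKM in Dilkhush, PR10.9 was 0.25 against 9.22 and PR10.3 was 8.34 against 64.7 (-2.81). Against that direction the chitinases CHI4D and chit1a were 164 against 22.6 RPKM and 153 against 21.3 RPKM, both called. CYP716A15, a triterpene-oxidizing cytochrome P450, was 3.50 against 60.1 RPKM (-3.76), OMT2.1 was 0.28 against 10.94 and IFRL3 was 0.86 against 12.3. Stilbene synthase rows were below 5 RPKM in all leaf columns, with a median of -1.37 (percentile 1.43, or 5.18 with a pseudocount of 0.1). An STS row was 0.86 against 4.63 RPKM and VINST1 was 0.044 against 1.70. FLS1 was 105 against 26.1 RPKM, MYB12 6.56 against 7.69, PSBP1 2084 against 1758, PSBP2 74.7 against 95.1, 4CL 112 against 116, CCOAMT 58.7 against 60.4, PL1 65.9 against 95.1 and HSP101 31.9 against 19.3.

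Of 11271 rows at the floor, 292 were called higher and 165 lower in Bangalore blue than in Dilkhush leaf, 457 in all. The count was 715 without the floor and 268 where 2 columns had to reach 5 RPKM. The unnamed LOC100251335 was 51020 RPKM in Bangalore blue leaf, 2.11 in Red globe and 3.33 in Dilkhush leaf.

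Red globe leaf against Dilkhush leaf showed GST4 at 162 against 53.2 RPKM (1.59), FAOMT at 21.0 against 9.32 (1.09) and UFGT at 11.6 against 7.87, with F3'5'H at 12.5 against 29.3 (-1.17), F3'H at 25.0 against 48.7, LDOX at 686 against 881 and DFR at 233 against 302. None of the 9 anthocyanin rows was called, and the median of -0.38 lay inside the central range (percentile 8.31), or at percentile 2.21 after quantile normalization. Early flavonoid rows had a median of -0.37 (percentile 17.22), with F3H at 322 against 625 RPKM and CHS3 at 70.5 against 135. MYC1 was 15.1 against 24.7 RPKM, MYCA1 41.9 against 68.5 and MYBC2-L1 8.78 against 18.4. MYB4A, MYB4B and MYBC2-L2 were 31.9 against 27.6, 15.6 against 18.1 and 49.3 against 43.0. MYBA6 and MYBA7, which the activator list left out, were 21.5 against 17.4 and 4.32 against 4.07 RPKM. Activator, repressor, proanthocyanidin, stilbene and sugar transport medians had percentiles of 9.14, 46.96, 2.79, 7 and 68.87. LAR1 was 15.1 against 28.3 RPKM and LAR2 63.6 against 130, an STS row was 0.82 against 4.63 and VINST1 0.39 against 1.70. The invertase NIN1 was called higher (2.26).

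FLS1, the flavonol synthase, was called higher at 252 against 26.1 RPKM (3.22) in Red globe leaf, and MYB12 was 10.56 against 7.69. CBF4 was 26.3 against 0.28 RPKM (4.42), BAP1 55.5 against 3.12, the lipoxygenase LOXO 121 against 20.8, SIUP1 99.7 against 12.1 and MLO3 13.1 against 0.89. The defence list had a median of -1.20 (percentile 0), with 9 of 13 rows lower and 4 higher, 2 called lower and 0 called higher. Among the higher rows, CHI4C was 28.5 against 9.37 RPKM and CHIT3 49.4 against 25.1. PR10.4 was 0.37 against 27.9 RPKM (-4.40), PR10.2 was 83.3 against 956 (-3.50), PR10.9 was 0.53 against 9.22 and PR-1 was 320 against 1272. VvUGTGT020 was 0.12 against 15.7 RPKM, CIPK16 1.48 against 19.3, CYP716A15 7.09 against 60.1 and HT5 7.92 against 51.4.

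The photosynthesis list had 2 rows, too few for a percentile, and neither was called. PSBP1 was 494 RPKM in Red globe leaf against 1758 in Dilkhush and PSBP2 was 54.4 against 95.1. Outside the list, the chlorophyll synthesis gene CHLH, chosen after its values were seen, was 138 against 629 RPKM. 4CL was 70.7 against 116 RPKM, CCOAMT 64.6 against 60.4, PL1 101 against 95.1 and HSP101 9.84 against 19.3. Of 11602 rows at the floor, 338 were called higher and 277 lower in Red globe than in Dilkhush leaf, 615 in all.

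Between Bangalore blue and Red globe leaf, GST4 was the most different of the named genes lower in Bangalore blue, at 2.58 against 162 RPKM (-5.51). FAOMT was 3.47 against 21.0 (-2.30) and was also called, and UFGT was 3.03 against 11.6. F3'H was 64.7 against 25.0 RPKM (1.34), F3'5'H 28.1 against 12.5, DFR 320 against 233 and LDOX 927 against 686. The anthocyanin median was 0.43 (percentile 94.81) and the early flavonoid median 0.65 (percentile 91.52). MYBC2-L1 was called higher, at 63.0 against 8.78 RPKM (2.71). MYC1 was 27.6 against 15.1, MYCA1 64.8 against 41.9, MYB4A 37.2 against 31.9, MYB4B 16.0 against 15.6 and MYBC2-L2 45.0 against 49.3. MYBA6 and MYBA7, which the activator list left out, were lower in Bangalore blue, at 6.29 against 21.5 and 0.68 against 4.32 RPKM.

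DHN1 was 72.0 against 1.43 RPKM (4.91) and CCD4b 19.9 against 0.20 (4.13). CIPK16, a kinase partner of calcium sensors, had 2 rows, at 57.1 against 1.48 and 50.7 against 1.75 RPKM. THI1-2, a thiamine synthesis gene, was 46.0 against 751 RPKM (-4.00). PSBP1, at 2084 against 494 (2.07), was called higher in Bangalore blue, and PSBP2 was 74.7 against 54.4. Defence rows were split at 6 higher and 7 lower with a median of -0.29 (percentile 19.57), and the activator, repressor, proanthocyanidin, stilbene and sugar transport medians had percentiles of 89.01, 66.68, 78.45, 33.55 and 20.43. The chitinase chit1a (LOC100232985) was 153 against 19.4 RPKM, PR10.2 545 against 83.3 and CHI4D 164 against 30.8. LAR1 was 62.7 against 15.1 RPKM, LAR2 76.5 against 63.6, CHS3 176 against 70.5, F3H 608 against 322, HT4 16.5 against 4.02 and HT5 24.0 against 7.92. Stilbene synthase rows were below 1 RPKM in both, with an STS row at 0.14 against 0.51 and VINST1 at 0.044 against 0.39. FLS1 was 105 against 252, MYB12 6.56 against 10.56, 4CL 112 against 70.7, PL1 65.9 against 101, CCOAMT 58.7 against 64.6 and HSP101 31.9 against 9.84. Of 11595 rows at the floor, 362 were called higher and 242 lower, 604 in all, or 399 where 2 columns had to reach 5 RPKM. Scaled to an equal total without transfer RNA, 316 were higher and 293 lower.

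Cultivar differences were then set side by side in both tissues over 23590 rows present in both tables. For Bangalore blue against Dilkhush, 79 rows were called in peel and in leaf, 63 in the same direction and 16 in opposite directions. For Red globe against Dilkhush 59 rows were called in both tissues, 39 alike and 20 opposite, and for Bangalore blue against Red globe 69 rows, 61 alike and 8 opposite. GST4 was among the opposite rows for Bangalore blue against Dilkhush. No interaction was tested, because the tables hold no replicate columns.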

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

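Of the tests in this part, those on anthocyanin genes and on GST4 were chosen after the values were seen, and those on rows low in Bangalore blue before. Differences between tissues were not tested, since each rests on 1 value per cultivar and tissue.

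Named genes were singled out where a cultivar difference was called in opposite directions in peel and leaf. For GST4, Bangalore blue minus Dilkhush was 7.69 in peel and -3.92 in leaf, 11.61 apart on the log2 scale. For PR10.3 the same difference was 2.57 in peel and -2.81 in leaf, 5.39 apart. For the hexose transporter HT5, Red globe minus Dilkhush was 3.84 in peel and -2.55 in leaf, 6.39 apart. For MLO11 it was 2.81 and -2.55, 5.36 apart, from peel values of 11.8 and 0.82 RPKM and leaf values of 1.47 and 13.5 RPKM.

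The low GST4 in Bangalore blue leaf (2.58 RPKM) cannot come from Bangalore blue reads that fail to align, since the same cultivar's peel had 2246 RPKM. A lower anthocyanin branch in that leaf is a candidate explanation. Of 10 other rows (the anthocyanin list with the leaf activators MYBA6 and MYBA7), 5 were lowest in Bangalore blue, or 50%, which does not decide it. These were FAOMT, UFGT, a further F3'5'H row, MYBA6 (6.29 RPKM against 21.5 in Red globe and 17.4 in Dilkhush) and MYBA7 (0.68 against 4.32 and 4.07). The remaining rows, DFR, LDOX, F3'H and the other F3'5'H rows, were lowest in Red globe. The mybA row, outside this count, was listed at 0 in Bangalore blue leaf, against 1.43 in Red globe and 0.58 in Dilkhush. The share of 50% thus depends on which rows are counted. Leaf age or a difference between cultivars stays open and was not tested.

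Anthocyanin genes were low in Dilkhush peel. The deposited column was not low as a whole: the median difference of all rows at the floor between Bangalore blue and Dilkhush was -0.087, against 5.22 for the list. RPKM scales each column to its own total, so this median cannot show whether RNA was lower before scaling. Dilkhush alleles that align poorly would be low in leaf as well. There the list median was -0.36, but it fell on a further F3'5'H row that was not measured in peel. Of the rows measured in peel, GST4, UFGT, FAOMT and, by little, F3'5'H were higher in Dilkhush leaf than in Bangalore blue leaf. DFR, LDOX and F3'H were lower there, so the genes were not low as a set in Dilkhush leaf. Less ripe Dilkhush fruit may still account for the pattern: of 9 ripening-induced GRIP genes, 4 were lower and 5 higher in Dilkhush than in Bangalore blue peel, or 44.4% lower, which leaves ripeness and cultivar unresolved. The cultivar difference in pigment that the series describes stays open as an untested biological explanation.

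Poor alignment of Bangalore blue reads to the reference was looked for as rows near 0 in that cultivar in both tissues. There were 0 such rows among 6214 with at least 10 RPKM in both other cultivars in both tissues. The counts were 0 of 6310 for Red globe and 2 of 6190 for Dilkhush. This argues against missing loci or strongly unlike alleles among those rows only. Rows low in another cultivar or tissue were not judged. Outside those rows, LOC104880013 was listed at 0 in Bangalore blue peel (217 RPKM in Red globe) and leaf (205 in Dilkhush). With 0 such rows there was no pattern for chance low values to explain, so chance could not be judged. Of only 3 peel rows near 0 in Bangalore blue, 0% were also near 0 in leaf. Rows at least 4-fold lower than both other cultivars in both tissues numbered 4 for Bangalore blue and 3 for each of the others. These were too few to decide whether reads aligned less well over many genes. Rows that low in peel numbered 73 for Bangalore blue, 57 for Red globe and 51 for Dilkhush. In leaf they numbered 24, 108 and 88, so the tissues pointed opposite ways.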

How the results depend on the processing

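No paired analysis was possible because the tables hold no replicate columns. For the same reason the replicate block, the fit of only the 2 cultivars compared, the robust variance model, leaving out each library, camera with an estimated correlation, fry and the interaction test were not run. List filters, equal-median list scaling and both settings without transfer RNA were chosen after the data were seen.

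Counts of called rows moved by over 1.5 times without the floor and with the filter on low values. Without the floor they were 878 for Bangalore blue against Dilkhush peel, 797 for Bangalore blue against Red globe peel and 715 for Bangalore blue against Dilkhush leaf. With RPKM of at least 5 in 2 columns they were 379 and 350 for Bangalore blue and Red globe against Dilkhush peel, 268 for Bangalore blue against Dilkhush leaf and 399 for Bangalore blue against Red globe leaf, by construction from fewer rows. With that filter fewer lists kept 3 rows, and 10 of 33 list medians lay outside the central range in place of 19 of 48. With a pseudocount of 0.1, 7 of 48 list medians moved by over 1.5-fold. The anthocyanin median of Bangalore blue against Dilkhush peel was 7.08 with that pseudocount and 4.62 with the filter, and that of Red globe against Dilkhush peel was 2.74 with the filter. The pseudocount also moved the stilbene median of Bangalore blue against Dilkhush leaf from -1.37 to -2.48. It moved the proanthocyanidin median of Red globe against Dilkhush peel from -0.85 to -1.49. No called difference of a named gene and no list median outside the central range changed sign under the settings run for it. For called genes this was all but fixed in advance. Another pseudocount cannot turn the sign of a single gene, and the scalings moved values by far less than the log2 size of 2 needed for a call. A difference near 0 that was not called did turn for F3'H between Bangalore blue and Red globe peel after scaling to equal medians (-0.03 to 0.0011).

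Scaling to an equal total without transfer RNA moved the median of all rows from -0.12 to 0.06 for Red globe against Dilkhush peel, from 0.03 to 0.15 for the leaves, and from -0.05 to -0.19 for Bangalore blue against Red globe leaf. The first of these then had 272 rows called higher and 272 lower, in place of 232 and 321. The share of higher calls moved from 55.0% to 59.5% for Red globe against Dilkhush leaf and from 59.9% to 51.9% for Bangalore blue against Red globe leaf. Of 173 differences of single genes, all 173 moved by less than 1.5-fold under each of the 3 scalings, and 37 moved by more with a pseudocount of 0.1. Equal-median and equal-total scaling multiply a whole column by 1 constant, and these shifts were small. For them the result was therefore fixed in advance and is no sign of robust genes. What depth limits is unknown, and genes near 1 RPKM are the least certain.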

Other observations

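Families here were formed after the data were seen, from symbols sharing a prefix on at least 4 rows. Of 90 medians in 15 families, 27 lay outside the central 95% of random lists, where 4.5 would by chance if rows within a family varied independently. They may not, since family members can be close copies with shared reads. The medians are also not independent of each other, since the Bangalore blue against Red globe comparison follows from the other comparisons. The PR and HT families repeat rows of the defence and sugar transport lists. The count therefore does not measure how many families differ.

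Aquaporins of the plasma membrane (PIP) were lower in Bangalore blue and Red globe peel than in Dilkhush peel. All 7 rows were lower in Bangalore blue, with a median of -1.65 (percentile 0.02), and all 7 in Red globe, with a median of -1.42 (percentile 0.04), under each of the 3 scalings tried. Only 1 of the 7 was called in Bangalore blue and 3 in Red globe, and PIP1;1 was 1.20 RPKM or less in every peel column. PIP1;3 was 1247 RPKM in Bangalore blue, 511 in Red globe and 2529 in Dilkhush. The 4 tonoplast aquaporin (TIP) rows had a median of -0.88 (percentile 1.99) in Bangalore blue against Dilkhush peel, with 2 higher and 2 lower and both lower rows called. In Red globe against Dilkhush peel their median was -1.66 (percentile 0.02), with 3 lower and 1 higher. In Bangalore blue against Dilkhush TIP1;2 was 134 against 770 RPKM and TIP2;1 was 876 against 518. In leaf the PIP medians were 0.12 (percentile 80.03) and -0.16 (percentile 18.44). Isoflavone reductase-like genes had a median of -1.86 (percentile 0) in Bangalore blue against Red globe peel, with 4 of 5 rows lower and 2 called. IFRL1 went the other way, at 1.63 against 0.026 RPKM.

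Among pathogenesis-related PR-1 and PR10 genes, all 7 rows measured in leaf were lower in Bangalore blue and in Red globe than in Dilkhush. The medians were -2.13 (percentile 0) and -1.99 (percentile 0.01), with 3 rows called in Bangalore blue and 2 in Red globe. These rows are part of the defence list described above and are not a separate observation. In peel 5 of 8 rows were higher in Bangalore blue than in Dilkhush, with a median of 0.29 inside the central range (percentile 94.46). In Red globe peel 6 of 8 rows were higher, with a median of 1.18 (percentile 100), while the PR-1 row was 0.71 against 670 RPKM. MYB14, a stilbene synthase regulator, was 12.5 RPKM in Bangalore blue peel, 4.71 in Red globe and 1.25 in Dilkhush, whereas the stilbene synthase VINST1 was 3.48, 13.0 and 0.13.

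Calcium-sensor kinase genes (CIPK) had a median of 0.40 (percentile 99.97) in Bangalore blue against Dilkhush leaf, with 13 of 19 rows higher. In Red globe leaf, ZEP and NDHM were 40.6 and 13.6 RPKM against 122 and 32.0 in Dilkhush and 137 and 56.8 in Bangalore blue.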
